A study of Rattus norvegicus with 13 samples.

How the data were processed

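The study measured microRNAs (miRNAs), short RNAs that bind messenger RNAs and lower their output, in fat of female Sprague Dawley rats. Per the labels, total RNA was extracted with a miRNeasy kit, 100 ng of it was labelled with the dye Cy3, and each sample was hybridised to an Agilent 1-colour rat miRNA array. The 7 control arrays came from daughters of fathers on standard chow and the 6 others from daughters of fathers on a high-fat diet, as the sample titles and treatments give them. The labels name no litter, father or fat depot, and each title carries its own animal number, so no samples were paired and sisters, if any, could not be modelled. The p-values then measure the spread between these animals as labelled.

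Per the file headers, the authors scanned each array and read it with Agilent Feature Extraction 10.7.3.1 on a grid of genome build rn4. The spot values used here are background-subtracted intensity on a linear scale, not normalized between arrays, per the file headers and the values. Feature Extraction also gave an intensity per miRNA, its total gene signal, in the deposited files. The deposited value table holds log2 of that total gene signal, blank where the miRNA was not detected, with no normalization between arrays. Its column medians ran from 6.95 (HFD 663) to 7.77 (control 662), and its scale and lack of centring were found by setting each column against the array's own scanner values. The submitters' processing notes name RMA and Partek without a role, and no trace of RMA was seen in the values. Of the 2569 values in the table, 26 differed from log2 of the total gene signal by more than 2e-04, and the table served only as an alternative.

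Control spots and spots with an outlier flag were left out, and 13540 spots of 1644 probes for 677 rat miRNAs remained before the flags were applied. Each probe had 5 to 20 spots, and each miRNA 1 to 4 probes. The unflagged spots of a probe were averaged, divided by the array's 75th percentile over the 260 probes detected on all 13 arrays, floored at 0.0197 (log2 -5.67) and taken to log2, and the probes of a miRNA were averaged. The floor was the median over arrays of the 1st percentile of the scaled signal of spots well above background. Values at the floor have no order. A miRNA counted as detected on an array where at least 1 probe was well above background in at least 0.5 of its spots, and was tested where it was detected on at least 6 arrays. This left 176 miRNAs. A log2 level is thus relative to the bright probes of the same array, and levels of different miRNAs were not set against each other, because probes differ in brightness. miRNA names are those of the array design.

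The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Before the data were examined, 17 lists of miRNAs were fixed: the let-7, miR-29, miR-30, miR-181, miR-15/16 and miR-34 families, the miR-17-92 cluster with its paralogs, the imprinted Dlk1-Dio3 cluster, miRNAs that promote or restrain adipocyte differentiation, those of insulin signalling and obesity, those of brown and beige adipocytes, and markers of muscle, blood cells, endothelium, epithelium, and liver, pancreas, kidney and brain. The 14 lists with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01, and also with an estimated correlation and with fry. Marker means and detected miRNAs per array were compared by two-sided exact permutation tests over all 1716 splits of the arrays, whose smallest possible p is 0.000583. The rule for named miRNAs, fixed at the same time, took the 10 lowest p in each direction, up to 4 members of each list by p, and the 5 with the brightest mean signal, and it named 72 miRNAs. Others are named only with the statement that they were chosen after their values were seen.

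The fit and the list test were tested on 20 simulated data sets drawn from the real means and residual SDs of the 176 miRNAs, 7 arrays against 6, with independent normal noise and 40 changed miRNAs, 10 of each size. The share of changes recovered was 53.5% at a log2 change of 0.25, 83.5% at 0.5, 95% at 1 and 99% at 2. With 40 of 176 miRNAs changed at once, the Benjamini-Hochberg cutoff is easier to pass than where few miRNAs change. These shares are therefore too high for a lone change, which was not simulated. Of the calls, 4.2% were false, and with no change simulated 0 calls were made. A list of 8 miRNAs shifted by 0.2 was called in 100% of the simulations, and 0 other lists were. Real miRNAs vary together and arrays can stand apart. For the real arrays, the recovery of changes and of the list is therefore likelier too high than too low, and the false calls likelier too few. With random splits of the real arrays, 63 of 100 gave at least 1 list past the threshold.

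The alternatives were other scalings (the percentile over all probes, the median, quantile normalization, normexp background with an offset of 50, RMA-like processing), the total gene signal, the brightest probe, the deposited table, other detection filters and floors, the slide or the range of animal numbers as a block, trended robust eBayes, arrayWeights, and each array left out. Alternatives chosen after seeing the data left out arrays rich in muscle miRNAs, used the muscle markers as a covariate, put the 26 table values back, tested whether the effect differed between slides, or ran the estimated correlation and fry where other lists were called. Normexp used the median spot signal. Barcodes placed 8 arrays on one slide and 5 on another, each with both groups, and all arrays were scanned on one day. Gene coordinates were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.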

Results

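MiRNA levels were measured in the fat of 13 adult daughters of male rats, 7 with control fathers that ate standard chow (9% as fat) and 6 with fathers that ate a high-fat diet (43% as fat). Mothers and daughters ate chow, the fathers were mated at 15 weeks of age, and the daughters' fat was taken at 14 weeks. The design asks whether a father's diet is followed by other miRNA levels in the fat of daughters, which the submitters describe as glucose intolerant at unaltered body weight when the father was fat-fed. The sources used here do not name the fat depot. Of 677 rat miRNAs on the array, 206 were detected on at least 1 array and 176 on at least 6 arrays. Each array detected between 154 (control 627) and 196 (HFD 663) miRNAs, with 20% to 25% of spots well above background and 0 saturated spots.

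Levels of most miRNAs lay close together in daughters of high-fat-diet fathers and of control fathers, and no miRNA passed the test. The lowest p belonged to miR-214, which shares a gene cluster with miR-199a and is known from mesenchymal cells. Its mean log2 level was -2.82 ± 0.28 (SD, n = 7) in control fathers' daughters and -3.20 ± 0.14 (SD, n = 6) in high-fat-diet fathers' daughters, and all 6 of the latter lay below the control mean. This is a log2 difference of -0.37 ± 0.12 (SE), or 0.773-fold, with an unadjusted p of 0.00871 and an adjusted p of 0.965 in limma. The next was miR-193*, from the opposite strand of the miR-193 precursor, at -5.31 ± 0.053 (SD, n = 7) in controls and -5.20 ± 0.072 (SD, n = 6) in the other group. It was 1.08-fold higher, above the control mean in 6 of 6 arrays, with an unadjusted p of 0.0168 and an adjusted p of 0.965 in limma. miR-193* lay near the floor of -5.67, at the floor on all arrays when that was raised 4 times, and its log2 difference ran from 0.026 with normexp to 0.25 with the deposited table.

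Over the 176 miRNAs tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.965. At an unadjusted p under 0.05 there were 2 miRNAs, where chance gives 8.8. Differences were higher for 91 miRNAs and lower for 85, with a median SE of 0.085. The 95% interval of the difference lay within 1.5-fold either way for 154 miRNAs and within 2-fold for 165. These counts include miRNAs at the floor on many arrays, where the floor narrows the interval. miR-379, at the floor on 10 arrays, had an interval of 0.86-fold to 1.03-fold. Its log2 difference ran from -0.53 to 0.0046 over the alternatives. That of miR-194, at the floor on 8 arrays, ran from -0.0043 to 0.38. For such miRNAs a narrow interval does not show that the levels lay close together.

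**Figure D1:**
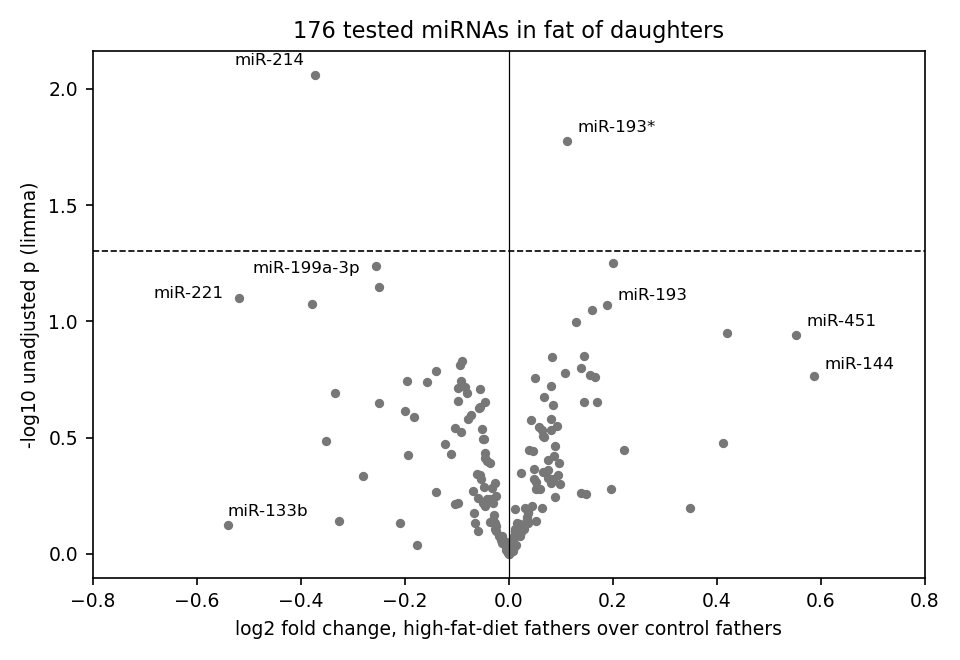
Log2 fold change of each of the 176 tested miRNAs (x axis, high-fat-diet fathers over control fathers) against -log10 of the unadjusted limma p (y axis), with the dashed line at 0.05. Only miR-214 and miR-193* lie above the line, and neither passed after adjustment.

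On the lower side, miR-199a-3p differed by -0.26 ± 0.12 (SE) and miR-199a-5p by -0.38 ± 0.20 (SE). miR-221, known from vessel cells and preadipocytes, differed by -0.52 ± 0.27 (SE), miR-23b by -0.25 ± 0.13 (SE) and its cluster neighbour miR-27b by -0.19 ± 0.14 (SE). Further lower miRNAs were miR-99b at -0.14, miR-324-5p at -0.093, miR-152 at -0.092 and miR-455* at -0.089, the last at the floor on 7 of 13 arrays. One control array, 658, held the highest level of several of these. Without it, miR-214 differed by -0.27 (unadjusted p = 0.00164, adjusted p = 0.289 in limma), miR-221 by -0.26, miR-199a-5p by -0.20, miR-23b by -0.16, miR-27b by -0.11 and miR-455* by -0.041. miR-214 differed by -0.24 with RMA-like processing and by -0.22 without the 5 arrays of high miR-133b, among them control 658. No miRNA passed without control 658, and adjusted p values over all alternatives for miR-214 ran from 0.289 to 1.

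On the higher side, miR-193 itself differed by 0.19 ± 0.10 (SE), which is 1.14-fold, and miR-365, from the same cluster, by 0.14 ± 0.093 (SE). The red blood cell miRNAs had the largest mean differences among the 10 lowest p on this side, with miR-451 at 0.55 ± 0.33 (SE) and miR-144* at 0.42 ± 0.25 (SE). miR-144* was at the floor on 3 control arrays and 0 HFD arrays, so the floor sets the size of its difference in part. miR-3545-3p stood at 0.20, miR-322 at 0.16, miR-378* at 0.14, miR-708 at 0.13 and miR-770* at 0.082, and the last was at the floor on 9 of 13 arrays. Without HFD 624, miR-365 differed by 0.064, miR-708 by 0.073 and miR-3545-3p by 0.13. miR-770* differed by 0.040 without HFD 620, miR-144* by 0.28 without HFD 663 and miR-322 by 0.24 without HFD 629. None of the higher miRNAs passed the test, and miR-451 differed by 1.06 without the 5 arrays of high miR-133b. That removal took out the controls of highest miR-451 (658, 662 and 664), while HFD 660 and 663, also high, stayed in. The larger difference thus depends on which arrays were removed. The 5 miRNAs of brightest mean signal differed little over all arrays, with let-7f at 0.031 ± 0.064 (SE), let-7a at -0.0090 ± 0.071 (SE), miR-23a at -0.0021 ± 0.069 (SE), miR-26a at -0.032 ± 0.048 (SE) and let-7c at -0.026 ± 0.075 (SE). All 5 took opposite directions on slides 1 and 2: let-7f -0.062 and 0.19, let-7a -0.12 and 0.17, miR-23a -0.13 and 0.18, miR-26a -0.059 and 0.017, and let-7c -0.15 and 0.19. None of the 5 passed the test of a difference between slides (limma interaction, adjusted p from 0.217 for miR-23a to 0.728 for miR-26a).

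**Figure D2:**
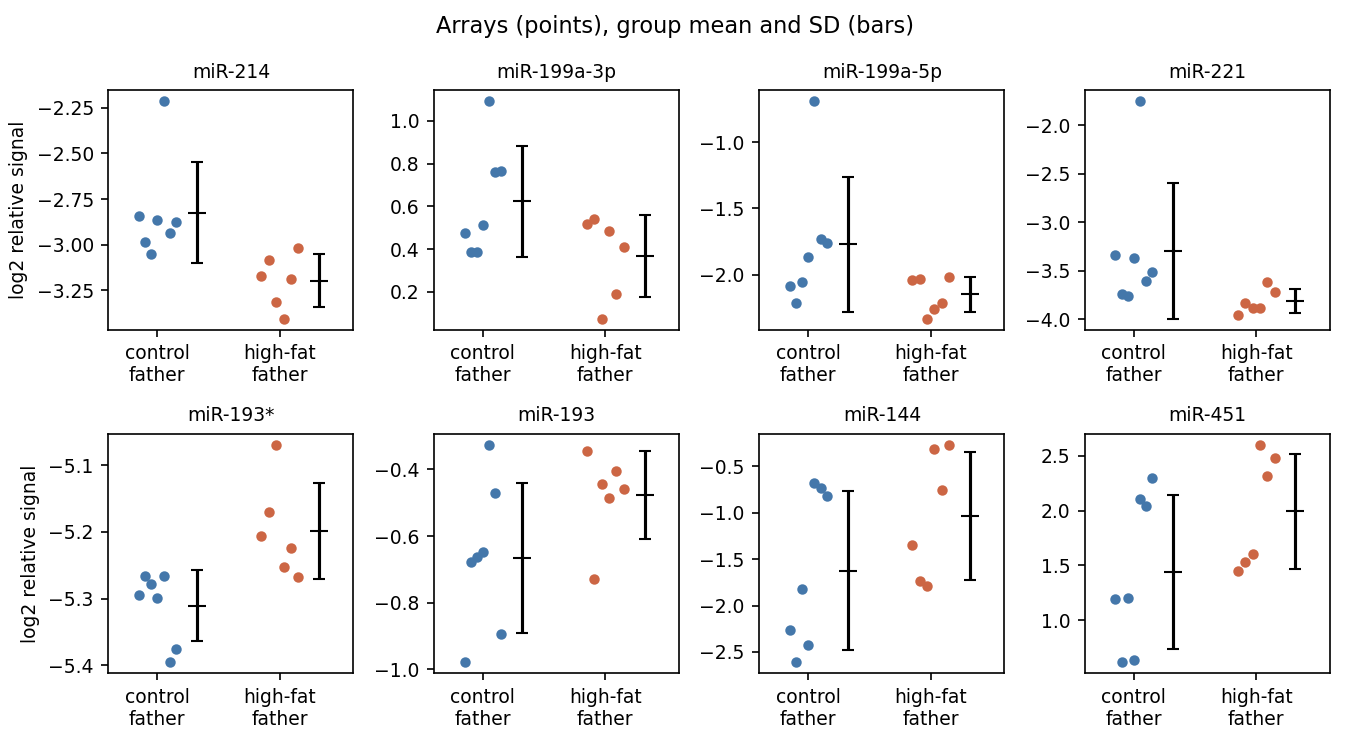
Log2 relative signal (y axis, a separate scale in each panel) of 8 named miRNAs on each of the 7 control-father arrays and 6 high-fat-diet-father arrays, with the group mean and SD beside the points. The highest control point of miR-214, miR-199a-3p, miR-199a-5p and miR-221 is array 658, and points of the groups overlap in each panel.

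Of the 17 fixed lists, 14 had at least 3 tested members, and only miRNAs of brown and beige adipocytes passed the list test with a preset correlation (camera, adjusted p = 0.0181), a call lost with an estimated correlation (adjusted p = 0.448) and by fry (adjusted p = 0.983). Of its 8 tested members 7 were higher and 1 lower, with a median log2 difference of 0.16 and a mean of 0.098. In limma 0 members passed, also when adjusted over the list alone. miR-193 and miR-365, which support brown fat formation, stood at 0.19 and 0.14, miR-378 at 0.16 and miR-203 at 0.17. Within slides 1 and 2, miR-193 differed by 0.29 and 0.027, miR-365 by 0.069 and 0.27, miR-378 by 0.29 and -0.031, and miR-203 by -0.034 and 0.48. miR-196a at 0.41 ± 0.41 (SE) and miR-196b at 0.20 ± 0.30 (SE), named after their values were seen, took their low control values from array 658. Without that array miR-196a differed by 0.050 and miR-196b by -0.076, 6 of 8 members were higher, and the median was 0.096. The member that was lower, miR-133b at -0.54 ± 1.67 (SE), is a muscle miRNA known to hold back brown fat formation. The list test did not pass when control 622 (adjusted p = 0.0580), control 658 (0.144), HFD 619 (0.104) or HFD 629 (0.0638) was left out, nor within either slide (0.215 and 0.248), where the median differences were 0.053 and 0.20. It was also lost with the deposited table (0.444), with arrayWeights (0.0557), with no detection filter (0.182), with the muscle markers as a covariate (0.0809) and without the 3 muscle-rich arrays (0.0511). The covariate was the mean of miR-1, miR-133b and miR-499, so it contained the list member miR-133b. The median difference was 0.14 without control 622, 0.12 without HFD 619 and 0.20 without HFD 629. It was 0.19 with the deposited table, 0.14 with arrayWeights, 0.067 with no filter, 0.16 with the covariate and 0.19 without the 3 arrays. Within the lower and upper ranges of animal numbers the median was 0.16 and 0.087, and the list did not pass (0.190 and 0.294). With the preset correlation, the let-7 (towards lower, adjusted p = 0.0192) and miR-17-92 (towards higher, 1.8e-05) lists passed within slide 1, and the miR-29 (towards lower) and miR-15/16 (towards higher) lists (both 0.0461) within the upper range. With an estimated correlation these were 0.762, 0.762, 0.690 and 0.690, and 0 lists passed there by it or by fry.

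The other lists had no member past the test, whether adjusted over all tested miRNAs or adjusted over the list alone, and none passed with either correlation or by fry over the 176 tested miRNAs of all 13 arrays without a block. With no detection filter, over all 677 miRNAs, the promoting (adjusted p = 0.000245), restraining (0.00145), let-7 (0.00145) and miR-29 (0.00371) lists passed camera with the preset correlation, each towards lower. Only 206 of the 677 were detected on any array, and their median difference with no filter was 6.0e-16 over all 677. The lists were thus set against mostly undetected miRNAs. With an estimated correlation the adjusted p of these 4 lists was 0.0667, 0.0491, 0.292 and 0.151, so only the restraining list passed, and by fry 0 did (adjusted p = 0.935). Of 9 tested members known to restrain adipocyte differentiation 6 were lower, with miR-221 at -0.52, miR-222 at -0.33 (at the floor on 8 of 13 arrays), miR-27b at -0.19 and miR-125b-5p at -0.072 (camera adjusted p = 0.235). miR-222 was at the floor on all 6 HFD arrays, so the floor sets the size of its difference in part. miR-125b-5p differed by -0.037 without control 656. Without control 658, miR-222 differed by -0.091, miR-27b by -0.11, miR-21 by -0.044 and miR-143 by -0.023. Those known to promote it were split, 10 of 18 higher, with miR-378 at 0.16, miR-26b at -0.050, miR-21 at -0.12 and miR-143 at -0.35 (adjusted p = 0.902), but 4 of 18 were higher with the total gene signal. In the list of insulin signalling and obesity, 9 of 13 were higher, with miR-126 at 0.082 and miR-29a at -0.097 (adjusted p = 0.685). miR-29a differed by -0.049 without HFD 663, and miR-126 by 0.052 without control 664 and by 0.13 without HFD 629. The let-7 family stood at a median of -0.025 with 2 of 8 higher, let-7i at -0.055, let-7e at -0.042 and let-7d at -0.030 (adjusted p = 0.685). Within slides 1 and 2, let-7i differed by -0.19 and 0.15, let-7e by -0.16 and 0.16, and let-7d by -0.10 and 0.094. Without control 627, let-7i differed by -0.022 and let-7d by -0.0040. Of the miR-17-92 cluster and its paralogs 9 of 9 were higher, by a median of 0.045, with miR-19a at 0.095, miR-17-5p at 0.076, miR-93 at 0.065 and miR-25 at 0.049 (adjusted p = 0.353), but 4 of 9 with the total gene signal. These named members took opposite directions on slides 1 and 2: miR-19a 0.33 and -0.26, miR-17-5p 0.17 and -0.061, miR-93 0.16 and -0.060, and miR-25 0.16 and -0.11. miR-17-5p differed by 0.024 without HFD 629, miR-19a by 0.036 without control 656 and miR-25 by 0.023 without control 631. With the preset correlation the miR-17-92 list passed with the number range as a block (adjusted p = 0.0481), without control 664 (0.0180), without HFD 624 (0.0203) and without the 5 arrays of high miR-133b (0.00477). With an estimated correlation these were 0.816, 0.480, 0.829 and 0.667, and 0 lists passed in these settings by it or by fry.

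In the miR-29 family 1 of 5 was higher, with miR-29b at -0.069 (-0.0011 without control 658), miR-29c at -0.028 and miR-29a* at -0.027 (camera adjusted p = 0.393). In the miR-30 family 7 of 8 were higher, with miR-30b-5p at 0.067, miR-30e* at 0.037, miR-30e at 0.029 and miR-30a* at 0.024 (adjusted p = 0.568), but 2 of 8 with the total gene signal. miR-30b-5p differed by 0.036 without HFD 619. Within slides 1 and 2, miR-30b-5p differed by 0.037 and 0.13, miR-30e* by 0.17 and -0.15, miR-30e by 0.17 and -0.19, and miR-30a* by 0.058 and -0.023. Of the miR-15/16 family 6 of 6 were higher, with miR-15b at 0.075, miR-16 at 0.047 and miR-322* at 0.016 (adjusted p = 0.353), but 3 of 6 with the total gene signal. miR-15b differed by 0.16 without control 664 and by 0.043 without HFD 660, and miR-16 by 0.025 without control 658. Within slides 1 and 2, miR-15b differed by 0.19 and -0.11, miR-16 by 0.054 and 0.044, and miR-322* by -0.011 and 0.087. In the imprinted Dlk1-Dio3 cluster 4 of 8 were higher, with miR-494 at 0.082, miR-379 at -0.080 and miR-127 at -0.18 (adjusted p = 0.987), and miR-379 was at the floor on 10 of 13 arrays and miR-127 on 5. miR-127 differed by -0.11 without control 662, miR-379 by -0.044 without control 664, and miR-494 by 0.051 without HFD 624 and 0.13 without HFD 663. The miR-181 family had 2 of 4 higher, with miR-181d at 0.082, miR-181a at 0.011, miR-181b at -0.0026 and miR-181c at -0.00048 (adjusted p = 0.685). Leaving out 1 array moved the difference by more than 1.5 times for 60 of the 72 named miRNAs. The directions of 25 of the 72 named miRNAs turned under at least 1 alternative, among them let-7a, let-7c, let-7e, let-7f, miR-21, miR-23a, miR-29a*, miR-29c, miR-30a*, miR-30e, miR-30e*, miR-34a, miR-322*, miR-378, miR-379 and the miR-181 members other than miR-181d. Fits within a slide are not counted among these alternatives. Further named miRNAs took opposite directions on slides 1 and 2, such as miR-99b (-0.26 and 0.056), let-7i (-0.19 and 0.15) and miR-93 (0.16 and -0.060). Others, such as miR-214 (-0.30 and -0.45), kept theirs. The miR-34 family had only 2 tested members and no list test, miR-34b at 0.14 and miR-34a at 0.053. miR-34b was highest on HFD 663 (-4.49) and differed by 0.042 without that array.

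Markers of other tissues varied more between arrays than between diets. Skeletal and heart muscle miRNAs miR-1 and miR-133b reached log2 levels of 2.50 and 2.36 on control 662, 1.94 and 1.67 on control 664, and 2.74 and 2.61 on HFD 629, while the other 10 arrays lay between -5.24 and -1.28 for miR-1. These miRNAs made up 90.5% of the squared loading of the first principal component, which held 61.0% of the variance. The muscle list had 0 of 3 higher, with miR-499 at -0.10, miR-133b at -0.54 and miR-1 at -0.18 (camera adjusted p = 0.685), and its mean differed by -0.27 (exact permutation p = 0.863, n = 7 and 6). Without the 3 muscle-rich arrays, miR-133b differed by 0.14 and miR-1 by 0.65. All 3 list members took opposite directions on slides 1 and 2: miR-133b 1.97 and -3.92, miR-1 2.14 and -3.26, and miR-499 0.20 and -0.52. Blood cell markers were split, 3 of 8 higher, with miR-451 at 0.55, miR-144 at 0.59, miR-223 at -0.11 and miR-342-3p at -0.16 (camera adjusted p = 0.954), so the mean of the list, 0.095, and its median, -0.034, differed in sign. Without control 664, miR-223 differed by -0.045 and miR-342-3p by -0.086. Endothelial miR-126 and miR-126* stood at 0.082 and 0.086 (exact permutation p = 0.240 for their mean, n = 7 and 6), and epithelial miR-203 and miR-205 at 0.17 and -0.19 (exact permutation p = 0.916, n = 7 and 6). Of the liver, pancreas, kidney and brain markers 4 of 5 were higher, with miR-7a at 0.090, miR-192 at 0.097, miR-194 at 0.039 and miR-122 at 0.35 ± 0.72 (SE) (camera adjusted p = 0.457). Without HFD 620, miR-122 differed by -0.084 and miR-192 by 0.031, without HFD 624 miR-7a by 0.028, and without control 622 miR-205 by -0.075.

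**Figure D3:**
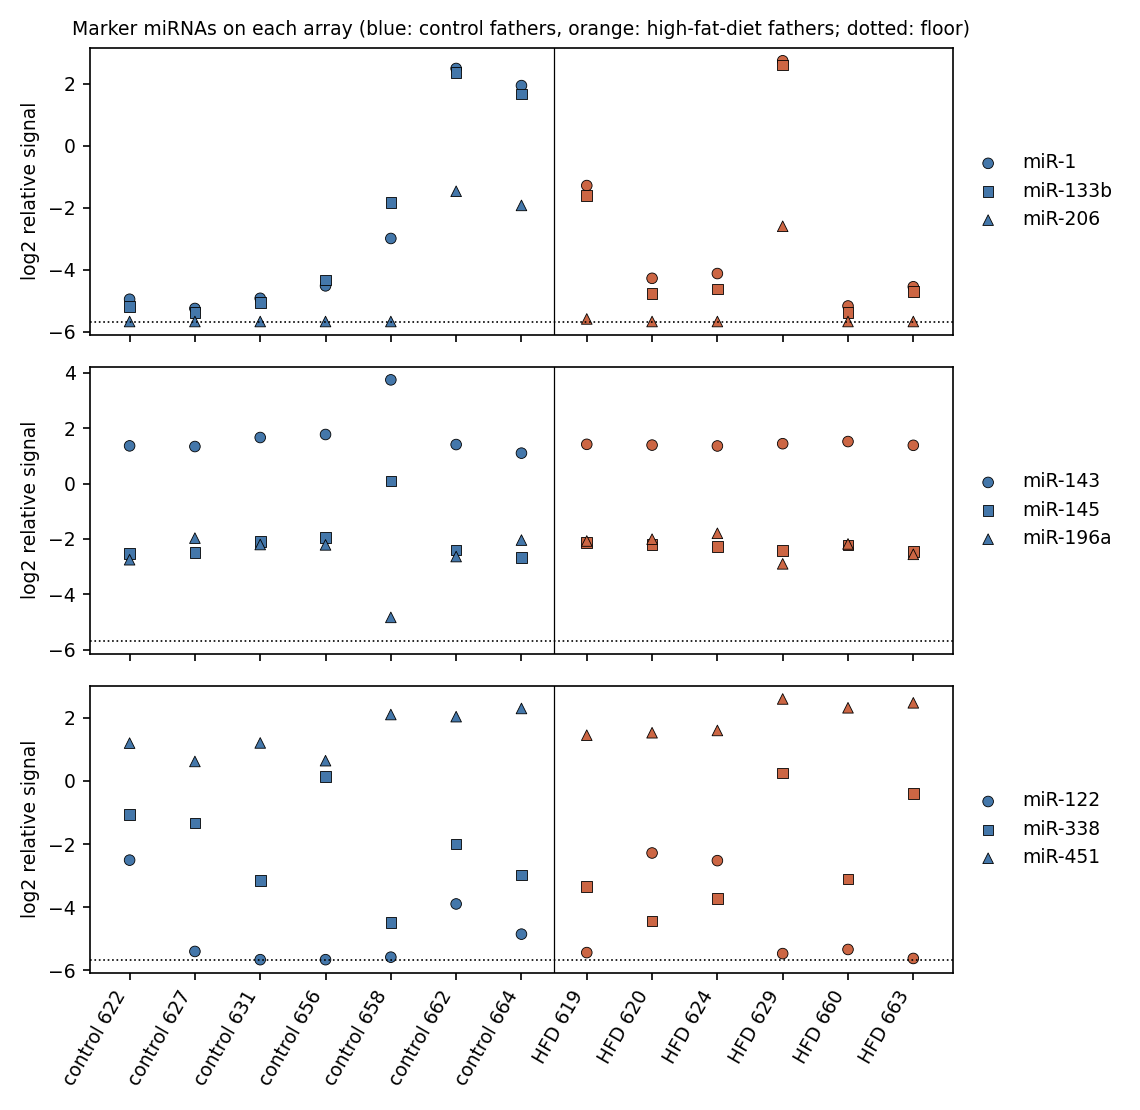
Log2 relative signal (y axis) of muscle, vessel, body-site and other marker miRNAs on each of the 13 arrays (x axis), control fathers left and high-fat-diet fathers right of the line, with the floor dotted. miR-1 and miR-133b are high on controls 662 and 664 and on HFD 629, and miR-143, miR-145 and miR-196a stand apart on control 658.

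The number of detected miRNAs was 168 ± 8.35 (SD, n = 7) in control fathers' daughters and 174 ± 15.0 (SD, n = 6) in the other group (exact permutation p = 0.372), and over the 9 such array measures compared the adjusted p was 0.916. Within the slides, limma called 0 miRNAs on either, with 17 at an unadjusted p under 0.05 on slide 1 (4 against 4 arrays) and 17 on slide 2 (3 against 2 arrays). miR-214 differed by -0.30 and -0.45 within slides 1 and 2, by -0.35 with the slide as a block, by -0.28 and -0.38 within the lower and upper range of animal numbers, and by -0.33 with that range as a block. miR-199a-3p differed by -0.011 and -0.48 and miR-199a-5p by -0.047 and -0.61 within the lower and upper range. miR-193* differed by 0.081 and 0.16 within the slides. miR-451 took opposite directions, 1.33 on slide 1 and -0.66 on slide 2, and so did miR-144, 1.5 and -0.80, and miR-144*, 0.95 and -0.42. Within the lower and upper number ranges miR-451 differed by 0.79 and 0.63 and miR-144 by 0.94 and 0.65, and with the range as a block by 0.72 and 0.81. On slide 2 the 3 controls were all from the upper range and the 2 other arrays from the lower, so slide 2 cannot part the father's diet from the number range. The difference between slides was tested after these values were seen, and it passed for miR-451 (limma interaction, log2 -1.99 ± 0.35 (SE), adjusted p = 0.0281) and not for miR-144 (adjusted p = 0.0661) or miR-144* (adjusted p = 0.154). At an unadjusted p under 0.05 this interaction test had 34 of 176 miRNAs, where chance gives 8.8.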

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

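The tests on control array 658 below were chosen before their results were seen, but the added margin of 1 SD of the other 12 arrays was set afterwards. In 146 groups of values, 16 had one array far from the rest of its group, where about 1 in 20, or 7.3, are so by chance. Of these, 7 were on control 658.

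Control 658 stood apart from the other control arrays in miR-143 (log2 level 3.74), miR-221 (-1.75), miR-222 (-3.87), miR-214 (-2.21), miR-199a-5p (-0.69), miR-29b (1.22) and miR-455* (-5.27). Against the median of the other 12 arrays, miR-143 was 5.08-fold and miR-145 5.37-fold, and miR-196a was 0.160-fold, the latter pair named after their values were seen. A vessel wall that brought its endothelium would be expected to raise miR-126, which was 1.34 on this array, inside the range of 1.33 to 1.70. No such rise was seen. Because miR-126 lay far above the floor on every array, a small added share might not show, so a vessel wall stays open. Smooth muscle alone was not tested. Fat from another body site stays an open candidate explanation. Of the 2 further Hox-cluster miRNAs, 1 lay outside the others' range: miR-10b at -0.085 against 0.18 to 0.51, with miR-10a-5p inside it. Against the median of the others, miR-10b was 0.79-fold and miR-10a-5p 1.02-fold. Some array must lie lowest for each miRNA, so this result decides little. A noisy array stays open, since its median absolute deviation of 0.161 lay above the others' 0.0763 to 0.156 by less than their SD of 0.022. The father's diet was not tested for this single array.

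On HFD 629, miR-322 was low (-1.21) and miR-34a low (-0.76), and miR-30a* was high (-3.24) among the high-fat-diet fathers' arrays. On HFD 620, miR-193 was low (-0.73). On control 664, miR-15b (-0.75) and miR-7a (-4.47) were high among the controls. Near the floor of -5.67, where the other arrays of the group had no order, miR-770* stood at -5.59 on control 627, miR-455* at -5.60 on HFD 660 and miR-379 at -5.65 on HFD 663.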

How the results depend on the processing

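The alternatives that left out the 3 or the 5 muscle-rich arrays, used the muscle covariate or put the table's altered values back were chosen after seeing the data. The count of miRNAs past the threshold stayed at 0 in limma under every alternative for the difference between the groups, with 1 to 13 miRNAs at an unadjusted p under 0.05 and a lowest adjusted p of 0.131, without HFD 629. It was also 0 within each slide and number range, with 8 to 17 unadjusted. In the separate test of a difference between slides, also chosen after seeing the data, 1 miRNA passed (34 unadjusted, where chance gives 8.8). The count of lists past the threshold was 1 (brown and beige adipocytes) in the main result and 0 with the deposited table (lowest adjusted p = 0.444), the same table with its altered values put back (0.0834), arrayWeights (0.0557), the 3 muscle-rich arrays left out (0.0511), the muscle covariate (0.0809), an estimated correlation (0.448) and fry (0.983). It was 4 with no filter, where the let-7, miR-29, differentiation-promoting and differentiation-restraining lists were called over all 677 miRNAs, and 2 with the number range as a block, where the miR-17-92 list was added (with an estimated correlation, run after seeing these calls, 1 and 0). Leaving out each array gave 0 to 2 lists. It was 0 without control 622, control 658, HFD 619 or HFD 629, and 2 without control 664 or HFD 624. With the 5 arrays of high miR-133b left out it was 1, but that list was the miR-17-92 cluster, and the adjusted p of the brown and beige list was 0.178. The median difference of the brown and beige list ran from 0.067 with no filter to 0.22 without control 662. The difference in detected miRNAs was 6.33, and 2 to 9.8 with each array left out. The cause of these changes was not tested, except where fewer arrays or other miRNAs entered by construction. No paired analysis was possible because the groups share no animal number. Signal over background limits miRNAs near the floor: with 4 times the floor, 19 of the 72 named miRNAs lay at it on all arrays and gave no value.

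Of 2418 values of the 72 named miRNAs under the alternatives, 2299 kept their direction and 119 did not, none of them past the threshold. Fits within a slide or a number range are not among the 2418, and further named miRNAs took opposite directions on the slides. All log2 differences among the 2418 that changed sign follow. With 4 times the floor miR-378* -0.00031 and miR-19a -0.0018. With the percentile over all probes miR-181a -0.0066 and miR-181c 0.0068. With the total gene signal let-7f -0.013, miR-30e* -0.0073, miR-30e -0.015, miR-30a* -0.019, miR-181a -0.032, miR-181c 0.18 and miR-322* -0.012. With RMA-like processing let-7a 1.7e-05, miR-23a 0.057, miR-29c 0.0098, miR-30a* -0.0077, miR-181b 0.0068 and miR-181c 0.030. With the number range as a block miR-181b 0.0026, miR-181c 0.036, miR-34a -0.0097 and miR-1 0.070. With arrayWeights miR-29a* 0.0067, miR-30a* -0.017, miR-181b 0.025, miR-181c 0.078, miR-34a -0.043 and miR-1 0.20. With the brightest probe miR-23a 0.0074 and miR-181c 0.047. With the deposited table let-7a 0.012, miR-23a 0.025, let-7c 0.0010, miR-378 -0.29, miR-181b 0.025 and miR-181c 0.25. With that table with its altered values put back let-7a 0.012, miR-23a 0.025, let-7c 0.0010, miR-181b 0.025 and miR-181c 0.25. With 0.5 times the floor miR-181b 0.0080 and miR-181c 0.063. With the median miR-181c 0.0047. With the muscle covariate miR-1 0.21. With normexp let-7a 0.0023, miR-23a 0.0092, miR-181c 0.0072, miR-322* -0.011 and miR-194 -0.0043. With quantile normalization miR-23a 0.041 and miR-29c 0.0086. With the slide as a block miR-181b 0.0034, miR-181c 0.0031 and miR-1 0.11. With the 3 muscle-rich arrays left out let-7a 0.0084, miR-30a* -0.044, miR-379 0.0037, miR-181b 0.048, miR-181c 0.0086, miR-133b 0.14 and miR-1 0.65. With the 5 arrays of high miR-133b left out miR-21 0.024, miR-29a* 0.0064, miR-30a* -0.029, miR-379 0.0046, miR-181b 0.032, miR-181c 0.090, miR-34a -0.092, miR-133b 0.12 and miR-1 0.38. With each array left out in turn, the ranges that crossed zero were let-7f -0.0016 to 0.070, let-7a -0.039 to 0.026, miR-23a -0.033 to 0.030, let-7c -0.065 to 0.0038, let-7e -0.085 to 0.0013, miR-29c -0.060 to 0.020, miR-30e* -0.013 to 0.075, miR-30e -0.027 to 0.076, miR-30a* -0.046 to 0.059, miR-181a -0.010 to 0.052, miR-181b -0.022 to 0.028, miR-181c -0.034 to 0.049, miR-322* -0.012 to 0.043, miR-34a -0.026 to 0.14, miR-499 -0.19 to 0.015, miR-133b -1.68 to 0.28, miR-1 -1.28 to 0.67 and miR-122 -0.084 to 0.73.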

Other observations

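The tests of muscle tissue, of the father's diet and slide as sources of it, of the table replacement, of blood and of the slide difference were chosen after their patterns were seen, while the predictions for the muscle covariate, an alternative chosen after seeing the data, and for the splits of the arrays were set before their results were seen. The miRNAs named here outside the fixed rule were chosen after their values were seen.

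Some miRNAs varied widely in level between arrays, and others were detected on only some of them. miR-338 reached 0.13 on control 656, 0.26 on HFD 629 and -0.39 on HFD 663, against -4.49 on control 658 and -4.44 on HFD 620, and miR-204 was likewise highest on HFD 663 (-1.95) and HFD 629 (-2.69). miR-9, known from neural tissue, was detected on 4 arrays, of which control 656 (-5.10), HFD 629 (-4.83) and HFD 663 (-5.04) were the highest, and miR-138 was detected on those 3 arrays. miR-122, the main miRNA of liver, lay at -2.51 on control 622, -2.28 on HFD 620 and -2.53 on HFD 624 and at or near the floor on most others. miR-200b, an epithelial miRNA, was detected on 4 arrays, controls 658, 662 and 664 and HFD 663.

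High miR-1 and miR-133b on controls 662 and 664 and HFD 629 were matched by the other muscle miRNAs. All 5 detected members of the muscle list were higher on each of these 3 arrays than on any of the other 10, as miR-1 and miR-133b, which picked the arrays, had to be, with miR-206 at -2.59 or above there and at -5.58 or below elsewhere, and miR-499 apart by little (control 664 -4.00, control 658 -4.01). Father's diet as the sole source is argued against, since 2 of the 3 arrays are controls. Slide alone does not account for all 3, since 1 of the 3 lies on slide 1, but a link to the slide stays open. Of the 5 arrays of high miR-133b, controls 658, 662 and 664 and HFD 619 lie on slide 2, and HFD 629 on slide 1. Skeletal muscle left in the dissected fat may account for the high miR-1 and miR-133b, as a hypothesis found on these arrays. Whether muscle widened the spread and hid differences stays open: in limma 0 miRNAs passed with the muscle covariate, without the 3 arrays or without the 5 of high miR-133b, but 5, 9 and 13 had an unadjusted p under 0.05, against 2, and the lowest adjusted p was 0.863, 0.391 and 0.309, against 0.965. Leaving out the 5 also removed all 3 controls of slide 2. Within slide 1 alone, limma had 17 miRNAs at an unadjusted p under 0.05. The removal of the 5 therefore cannot part muscle from slide.

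The deposited value table held 26 values, on all 13 arrays and in 22 miRNAs, that differ from log2 of the total gene signal. All 26 equal log2 of the number left when the characters 0.1 inside the signal are replaced by 1, so such a replacement is a candidate source. It made 9 values between 1021-fold and 1053-fold too high, such as miR-429 on control 662 (14.4 in place of 4.33), 6 by 101-fold, 9 by some 10-fold and 2 by under 1.1-fold. Such values fell on 12 control and 14 high-fat-diet spots of the table. miR-126* was altered on control 662 and HFD 619, and miR-378 on control 627, where its sign in the table-based comparison came out opposite (log2 -0.29, against 0.16).

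The red cell miRNAs miR-144, miR-144* and miR-451 had a mean difference of 0.52 (exact permutation p = 0.152, n = 7 and 6). More blood left in the fat of one group would be expected to raise white-cell markers too, but these differed by -0.055 ± 0.115 (SE), which does not decide it, because fat holds white cells of its own. miR-451 fell into higher and lower arrays in both groups, above 2 on controls 658, 662 and 664 and on HFD 629, 660 and 663, 5 of these 6 arrays being from the upper number range. Its difference, like those of miR-144 and miR-144*, took opposite directions on the slides (limma interaction adjusted p = 0.0281, 1 of 176 miRNAs passing and 34 at an unadjusted p under 0.05, where chance gives 8.8). The 34 also held miRNAs not of red cells, such as miR-34a, miR-23a and miR-92a. Because miRNAs vary together, the 34 are not independent. All slide 2 controls are from the upper range and its other arrays from the lower, and within each range miR-451 was higher (0.79 and 0.63), so slide and number range were not told apart.

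For the count of miRNAs past the threshold, 100 of 100 splits of the arrays gave as many as the real 0, with 4 the highest of the others; a count of 0 is reached by every split, so this comparison tests nothing. The real unadjusted count of 2 was reached by 89 of 100 splits, with a median of 6 and a highest of 36 in the others, and a split with 36 points to structure among the arrays. For the lists, 63 of 100 splits gave as many as the real 1, with 4 the highest of the others, so that chance cannot be excluded for the list call.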
